A study of Mus musculus with 2 samples.

How the data were processed

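DNase-seq was done on urinary bladder tissue of male B6CASTF1/J mice aged 14 days, in 2 libraries that the labels number as biological replicates 1 and 2. Replicate 1 is labelled as a male and replicate 2 as a pool of 3 males. Both were put in 1 group, bladder, so no conditions were compared, and means are given with the SD of the 2 replicates. For each library 4 tables were used: 2 peak lists, a footprint list and a track of false discovery rates (FDR). Each was made from 1 library without pooling, per the notes deposited with each sample, and uses the genome build mm10. The aligner, the peak and footprint callers and their versions are not given in the sources used here.

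The deposited peak lists give each peak's position and a signal value, which is the authors' own density per peak. How the authors normalized the signal is not given in the sources used here. In both lists of a library every signal was a whole multiple of 1 step, within 0.01 steps, which is what a single scaling factor per library leaves. The median peak held 132 steps in replicate 1 and 111 in replicate 2. If 1 step is 1 cut, its signal has a Poisson 95% interval of 0.575 to 0.815 in replicate 1 and 0.730 to 1.07 in replicate 2, which covers counting error only. The deposited FDR track holds a p-value or q-value of the authors, an FDR, for stretches of positions, and lists values of 0.05 or lower. All peaks of the looser list touched a stretch at an FDR of 0.05 or lower, and all peaks of the stricter list one at 0.001 or lower. The value deposited with each footprint was 0.01 throughout, so that footprints were used as positions only.

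Peaks of the replicates were joined into regions where they overlapped by at least 1 bp, and a region with peaks of both counted as shared. Chance overlap came from 1000 circular shifts within chromosomes, and for footprints also from 1000 random placements within shared regions. Signals were compared on the log2 scale of the deposited values, with no pseudocount, since all were above 0. Regions were assigned by their centre to promoters, within 1 kb of the TSS of any annotated gene, then to exons, introns or intergenic sequence. The annotation was GENCODE M21 and the sequence the RefSeq assembly GRCm38.p6, which is the build mm10. Coordinates are 1-based.

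A protein-coding gene's promoter was open where a shared peak lay within 1 kb of any of its TSSs, and its promoter signal was that of the strongest such peak. Open shares of 19 gene lists were set against all other protein-coding genes by Fisher's exact test, two-sided. Peaks within 10 kb of the gene body were counted, and a list's median was set against 10000 random lists matched on gene length decile (two-sided permutation p). Replicate signals were each divided by their median over shared regions, and a list's median log2 ratio was placed among 10000 random lists matched on mean signal. Motifs were 32 consensus sequences, searched on both strands in 200 bp windows at region centres and in random windows outside peaks and FDR 0.05 regions, matched on GC content in bins of 2 percentage points. For footprints the match had to be centred in the footprint, and the background was windows of the same width in the same accessible regions outside footprints. All p-values of a family were adjusted by the Benjamini-Hochberg method. Genes, regions and footprints are not independent replicates, so these tests describe the 2 libraries.

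Gene lists, motifs, tests and the rule for named genes were fixed before the data were examined. The rule named, from each list, up to 4 open genes with the highest mean promoter signal and up to 4 genes of a tissue list without a peak. It also named the 20 genes with most shared peaks per 100 kb among those with at least 10 peaks, and the 10 strongest shared regions outside promoters by mean rank. Some of the genes that the rule names, and 1 of the motifs, are not reported here. The alternatives were the stricter peak list, the stronger 50% of each replicate's peaks, equal numbers of peaks, other overlap rules, promoter windows of 500 and 2500 bp, a flank of 50 kb, 100 bp motif windows, promoter regions, other backgrounds, other scalings and each replicate alone. The stricter list was added after seeing the data for the genomic distribution, the peak density and the region motifs.

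The computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and blastn 2.17.0 for copies of regions. They were tested on simulated data. For peak overlap, a planted share of 50% was recovered as 50.0% over 19991 peaks. For promoter lists over 21938 genes, 4% of lists were called with nothing planted and 96.8% with an open share of 95%. For density lists over 21938 genes, 5.25% were called with nothing planted and 62.2% with peaks doubled. In both list simulations a call was an unadjusted p under 0.05, so the shares do not give the power at the adjusted threshold. For motifs in 3999 windows, 0 of 32 were called with nothing planted and 32 of 32 with matches planted in 10% of windows.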

Results

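Chromatin accessibility was measured by DNase-seq in the urinary bladder of male B6CASTF1/J mice at 14 days after birth. DNase-seq maps open chromatin by sequencing the ends that the nuclease DNase I leaves where DNA is not protected by nucleosomes. B6CASTF1/J mice are first-generation hybrids of the C57BL/6J and CAST/EiJ inbred strains. The 2 libraries form 1 group of 2 biological replicates, so the design holds no comparison between conditions. It allows a comparison of the replicates and a description of the regions that both hold. Replicate 1 is labelled as a male, in the singular, and replicate 2 as a pool of 3 males. Each library has a peak list whose peaks all touch its FDR 0.05 regions, which was used unless another is named, and a stricter list whose peaks all touch its FDR 0.001 regions. Peak signals were whole multiples of 0.00521 in replicate 1 and 0.00799 in replicate 2. If 1 step is 1 cut and both libraries were scaled to the same total, which no label records, replicate 1 was sequenced 1.54 times as deeply as replicate 2. The absolute depth is not given in the sources used here.

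The first question was how far the replicates hold the same open regions. Replicate 1 had 139821 peaks that covered 25.6 Mb, and replicate 2 had 82225 peaks that covered 16.2 Mb. Of the replicate 2 peaks, 91.0% overlapped a peak of replicate 1 by at least 1 bp, against 2.07% by chance. Of the replicate 1 peaks, 54.0% overlapped a peak of replicate 2, against 1.22% by chance. Both shares lay above all 1000 circular shifts of the peaks (one-sided permutation p = 0.001, the smallest that 1000 shifts can give). The union held 73164 regions with peaks of both replicates, 63999 with peaks of replicate 1 alone and 7321 with peaks of replicate 2 alone. The Jaccard index of the peaks' bases was 0.455. Overlap followed peak strength: 13.6% of the weakest quintile of replicate 1 peaks overlapped a replicate 2 peak, against 97.9% of the strongest quintile. In replicate 2 the shares were 67.6% and 99.8%. With the 82225 strongest peaks of each replicate, the shares became 77.3% for replicate 1 and 76.8% for replicate 2.

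**Figure D1:**
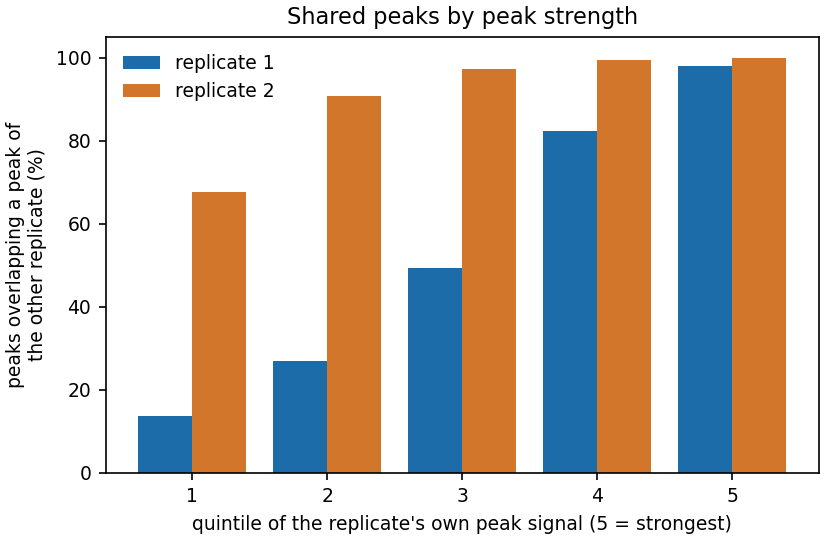
The bars give the percent of peaks that overlap a peak of the other replicate (y axis) for each quintile of the replicate's own peak signal (x axis, 5 is the strongest), with replicate 1 in blue and replicate 2 in orange. The share rises from 13.6% to 97.9% in replicate 1 and from 67.6% to 99.8% in replicate 2.

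Across the 73164 shared regions the log2 peak signals of the replicates had a Pearson correlation of 0.949 and a Spearman correlation of 0.931. These are correlations across regions, which are not independent replicates. The SD of the log2 ratio between the replicates was 0.42. The bases at an FDR of 0.05 or lower came to 40.3 Mb in replicate 1 and 26.2 Mb in replicate 2, and 93.2% of those of replicate 2 lay within those of replicate 1. Their Jaccard index was 0.580 at an FDR of 0.05, 0.592 at 0.01 and 0.594 at 0.001.

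Promoters made up the largest part of the shared regions relative to their share of the genome. A total of 27030 shared regions, or 36.9%, were centred within 1 kb of an annotated transcription start site (TSS), against 6.19% by chance, a 5.97-fold excess. Exons held 4.22% (1.28-fold), introns 30.7% (0.783-fold) and intergenic sequence 28.1% (0.548-fold). Each share lay outside the range of 1000 circular shifts (two-sided permutation p = 0.002, the smallest they can give). Median peak signal at promoters was 2.15 in replicate 1 and 1.73 in replicate 2. In introns it was 1.07 and 0.799, and in intergenic regions 1.07 and 0.791. The promoter share was 28.8% in replicate 1 alone and 36.5% in replicate 2 alone. The size of the excess depended on the window: it was 9.02-fold within 500 bp of a TSS and 3.38-fold within 2500 bp.

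Genes and peaks on the sex chromosomes were examined as a check of the labelled sex. The X chromosome carried 0.391 ± 0.0021 (SD, n = 2) times as many peaks per Mb as the autosomes, and its peaks were weaker. Median signal on X in replicate 2 was 0.496, against 0.895 on the autosomes, and in replicate 1 it was 0.3801 against 0.698. On the Y chromosome 136 peaks were called in replicate 1 and 73 in replicate 2. Of 8 listed Y-linked genes, 4 had a shared promoter peak. These were Ddx3y, an RNA helicase (signal 2.10 ± 0.18, SD, n = 2), Eif2s3y, a translation initiation factor subunit (1.97 ± 0.53), Uty, a histone demethylase (1.77 ± 0.67), and Kdm5d, a histone demethylase (1.15 ± 0.084). Usp9y, Zfy1, Zfy2 and the testis-determining gene Sry had none in either replicate.

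The next question was which cell types' genes had open promoters. A promoter was called open where a shared peak lay within 1 kb of any annotated TSS, and 14500 of 21938 protein-coding genes (66.1%) had one. Promoters of the 3 main bladder compartments were open more often than those of other genes. Urothelial genes were open in 26 of 28 cases, smooth muscle genes in 22 of 23 and fibroblast and stromal genes in 24 of 24. Their adjusted p were 0.00483, 0.00392 and 0.000891 by Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over 19 lists. The urothelial call held under every alternative. Smooth muscle did not pass with the stricter peak lists (19 of 23, adjusted p = 0.0813), with equal numbers of peaks (20 of 23, adjusted p = 0.0522) or with the stronger 50% of peaks (14 of 23, adjusted p = 1), by the same exact test. The stromal list did not pass with the stricter lists (20 of 24, adjusted p = 0.0592) or the stronger 50% (18 of 24, adjusted p = 0.198, Fisher's exact test for both). Genes are not independent replicates, so these tests describe the 2 libraries. The other genes were not matched on promoter GC content, so the test does not separate cell type from promoter type.

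Among urothelial genes the highest promoter signals were those of Klf5, a zinc-finger factor of epithelia (8.60 ± 0.95, SD, n = 2), and Gata3, a transcription factor of the urothelium (8.39 ± 2.1). Cdh1, which encodes E-cadherin (5.57 ± 1.6), and Sfn, which encodes stratifin (5.27 ± 1.6), followed. The genes of the uroplakins, the membrane proteins of the apical urothelial surface, were singled out after their values were seen. All of those listed were open: Upk2 at 4.47 ± 1.1, Upk3a at 3.80 ± 1.3, Upk1b at 3.30 ± 0.18, Upk1a at 2.01 ± 0.069 and Upk3b at 1.77 ± 0.19. Krt20, a keratin of superficial cells, and Trp63, the factor of basal cells, had a promoter peak in replicate 1 alone and were likewise named after their values were seen. The smooth muscle list was led by Tpm1, a tropomyosin (13.4 ± 1.6), Hspb6, a small heat shock protein (8.63 ± 3.0), Smtn, which encodes smoothelin (6.01 ± 0.065), and Mylk, the myosin light chain kinase (5.20 ± 2.0). P2rx1, a purinergic receptor gene named after its value was seen, had its promoter peak in replicate 1 alone. The stromal list was led by Col1a1, a collagen chain (4.91 ± 0.19), Bmp4, a secreted growth factor (4.43 ± 0.58), Gli1, a transcription factor of Hedgehog signalling (3.96 ± 1.2), and Pdgfra, a growth factor receptor (3.54 ± 0.85). The median signal over open promoters was 3.40 in the urothelial, 1.40 in the smooth muscle and 1.98 in the stromal list, against 4.62 over all open promoters.

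Genes of the endothelium, of nerves and glia and of immune cells were not open more often than other genes. Endothelial genes were open in 14 of 20 cases (adjusted p = 0.970, Fisher's exact test), with Vwf, the von Willebrand factor gene (3.42 ± 0.94, SD, n = 2), Esam (2.94 ± 0.99), Eng (1.64 ± 0.16) and Kdr (1.39 ± 0.43) highest. Pecam1, Emcn and Robo4 had no promoter peak in either replicate. Neural and glial genes were open in 9 of 16 cases (adjusted p = 0.619, Fisher's exact test), with the receptor gene Erbb3 at 2.71 ± 0.22, Hand2 at 1.67 ± 0.018 and Phox2a at 1.26 ± 0.011. Sox10 and Chat were among the 4 without a promoter peak in either replicate. Immune genes were open in 7 of 20 cases, less often than other genes (adjusted p = 0.0137, Fisher's exact test), with Coro1a at 3.75 ± 0.76, Lcp1 at 2.68 ± 0.56, Kit at 1.79 ± 0.21 and Ikzf1 at 1.05 ± 0.042. Another 7 immune genes had no promoter peak in either replicate, Csf1r, Cx3cr1, Adgre1 and Cd79a among them. The lower share of immune genes rested on replicate 2: with replicate 1 alone 13 of 20 were open (adjusted p = 0.699, Fisher's exact test). With a window of 2500 bp around the TSS, 10 of 20 were open (adjusted p = 0.141, Fisher's exact test).

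Of the 5 lists of tissues or cell types that a bladder should lack, 4 were open less often than other genes. Only 2 of 20 hepatocyte genes had an open promoter (adjusted p = 5.76e-06, Fisher's exact test): Hpd at 4.13 ± 1.2 (SD, n = 2) and Apob at 1.45 ± 0.35. The plasma protein genes Alb, Apoa1, Apoa2 and Ttr were among the 16 without a peak in either replicate. Germ cell genes were open in 3 of 16 cases (adjusted p = 0.000891, Fisher's exact test): Gdf9 at 11.9 ± 2.5, Tex14 at 7.72 ± 0.74 and Dazl at 4.49 ± 0.29. Ddx4, Sycp1, Sycp3 and Stra8 were among the 12 without a peak. Striated muscle genes were open in 7 of 20 cases (adjusted p = 0.0137, Fisher's exact test), led by Ckm (3.37 ± 0.89), Actn2 (1.96 ± 0.62), Ryr1 (1.06 ± 0.46) and Tnni3 (0.850 ± 0.094). Myh6, Tnnt2, Myl7 and the muscle-determining gene Myod1 were among the 11 without a peak. Erythroid genes were open in 5 of 14 cases (adjusted p = 0.0358, Fisher's exact test), with Nfe2 at 1.82 ± 0.12, Epor at 1.58 ± 0.11 and Tal1 at 0.968 ± 0.44. The globin genes Hba-a1, Hba-a2, Hbb-bs and Hbb-bt were among the 9 without a peak. With a window of 2500 bp around the TSS, only the hepatocyte and germ cell lists stayed below other genes. The erythroid call was also lost with equal numbers of peaks (adjusted p = 0.0749) and with a window of 500 bp (adjusted p = 0.0715, Fisher's exact test for both). The brain list, which holds glial genes such as Gfap and Olig2 beside neuronal ones, did not pass the test, with 13 of 20 open (adjusted p = 1, Fisher's exact test). Its genes were open less often than other genes with the stronger 50% of peaks (6 of 20, adjusted p = 0.0208, Fisher's exact test). Open ones included Snap25 (3.73 ± 0.58), Gfap (3.16 ± 1.1) and Dlx1 (1.89 ± 0.21), and Neurod6, Slc32a1 and Olig2 had no peak in either replicate.

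**Figure D2:**
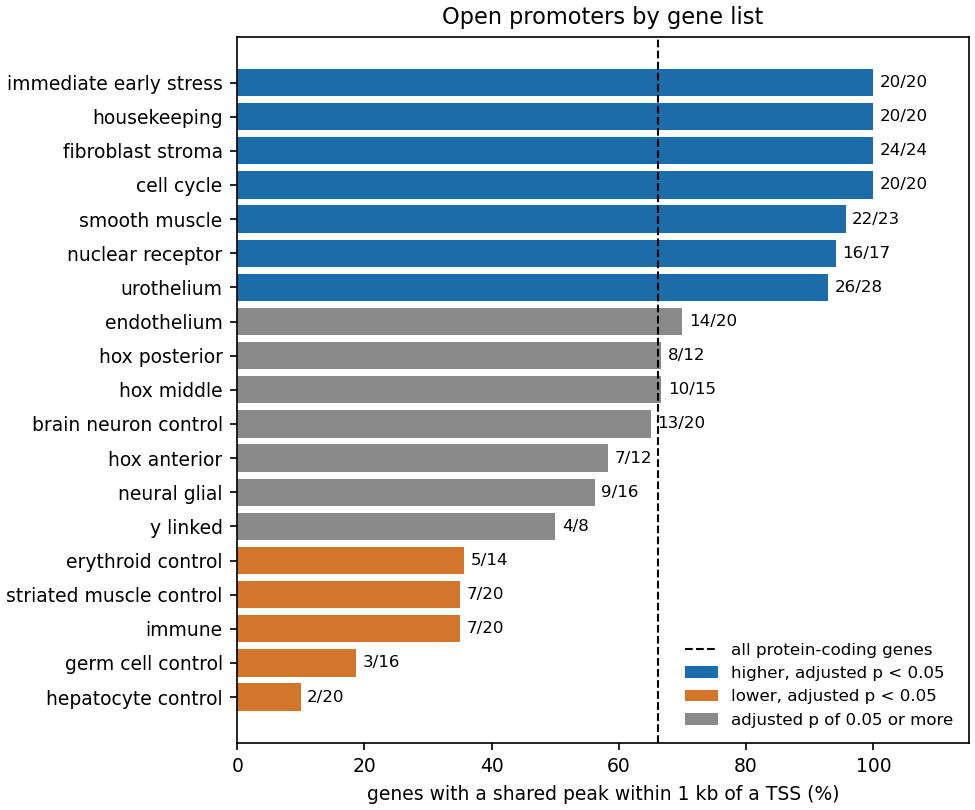
The bars give the percent of each list's genes with a shared peak within 1 kb of a TSS (x axis), with the count of open and listed genes beside each bar and the share of all protein-coding genes, 66.1%, as a dashed line. Blue lists were open more often and orange lists less often at an adjusted p under 0.05, from 24 of 24 stromal genes to 2 of 20 hepatocyte genes.

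Lists of widely used genes were open throughout. All 20 housekeeping, all 20 immediate-early and stress and all 20 cell cycle genes had an open promoter (adjusted p = 0.00145 for each, Fisher's exact test). Of the housekeeping genes, Rplp0 (14.9 ± 0.11, SD, n = 2), Actb (12.5 ± 0.078), Ppia (11.96 ± 0.52) and Vcp (11.9 ± 1.0) were highest. Of the immediate-early genes, the AP-1 subunit genes Jund (13.9 ± 1.9) and Jun (13.1 ± 2.6) led, before Klf6 (12.3 ± 0.60) and Atf3 (12.2 ± 2.0). Of the cell cycle genes, the cyclin gene Ccna2 (11.7 ± 1.6), the replication helicase genes Mcm5 (11.6 ± 1.5) and Mcm2 (8.76 ± 2.1), and the kinase gene Cdk1 (9.84 ± 1.4) led. Nuclear receptor genes were open in 16 of 17 cases (adjusted p = 0.0306, Fisher's exact test), a call lost with the stronger 50% of peaks (14 of 17, adjusted p = 0.128) and with equal numbers of peaks (15 of 17, adjusted p = 0.0722). Ppard (11.3 ± 2.2), the mineralocorticoid receptor gene Nr3c2 (10.3 ± 1.4), Rarg (9.53 ± 0.81) and the glucocorticoid receptor gene Nr3c1 (7.96 ± 2.2) were highest, and Nr2f2, named after its value was seen, had a promoter peak in replicate 1 alone.

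Peak density within 10 kb of the gene body separated the same compartments. A median urothelial gene had 5 shared peaks, against 2.5 in random lists matched on gene length (adjusted p = 0.00950, permutation over 10000 random lists, two-sided, adjusted over 19 lists). Smooth muscle genes had a median of 6 against 3 (adjusted p = 0.0152) and stromal genes 5 against 3 (adjusted p = 0.0213) in the same permutation test. The other lists that passed were immediate-early genes, 8 against 2 (adjusted p = 0.00380), nuclear receptor genes, 8 against 4 (adjusted p = 0.0152), and posterior Hox genes, 4.5 against 1.5 (adjusted p = 0.0228), all by permutation. The Hox genes lie in clusters, where windows of neighbours overlap and share peaks, while the random lists hold unlinked genes, so that the permutation p does not give the chance level of the Hox lists. The other 13 lists did not pass this permutation test. The number of lists that passed fell from 6 to 2, urothelium and immediate-early genes, with equal numbers of peaks per replicate, and to immediate-early genes alone with the stricter peak lists. With the stronger 50% of peaks, urothelium and immediate-early genes were the only ones of the 6 to pass. Smooth muscle and nuclear receptor genes did not pass with windows of 50 kb or without promoter peaks, and stromal genes did not pass with windows of 50 kb. The smooth muscle call was also lost with replicate 1 alone (adjusted p = 0.116, permutation). With replicate 1 alone, which has more peaks, the medians were 10 against 4 for urothelial, 9 against 4.5 for stromal, 16 against 7 for nuclear receptor and 13 against 2.5 for posterior Hox genes. Middle Hox genes, 4 against 2 in shared peaks (adjusted p = 0.109, permutation), passed with replicate 1 alone (11 against 3, adjusted p = 0.000950, permutation). They also passed with the stronger 50% of peaks (4 against 1, adjusted p = 0.0279, permutation). Housekeeping genes passed only with windows of 50 kb (adjusted p = 0.0104, permutation), and Y-linked genes had a lower density with either replicate alone (adjusted p = 0.0342 with replicate 2, permutation). Some Y-linked genes are neighbours with overlapping windows, on a chromosome with few peaks per Mb, while random lists come from all chromosomes. The permutation p therefore does not give the chance level of the Y-linked list either.

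Hox genes, which set position along the body axis, had an open promoter in 25 of 39 cases, and 5 had no promoter peak in either replicate. By position in the clusters, 7 of 12 anterior, 10 of 15 middle and 8 of 12 posterior genes were open, and none of these shares passed the test against other genes (adjusted p = 0.703, 1 and 1, Fisher's exact test). High anterior signals were those of Hoxa4 (4.19 ± 0.87, SD, n = 2), Hoxb4 (1.93 ± 0.70) and Hoxd3 (1.52 ± 0.010). In the middle list they were those of Hoxa7 (7.14 ± 0.24), Hoxa9 (5.07 ± 1.1), Hoxd8 (3.73 ± 0.81) and Hoxc5 (3.67 ± 0.98). In the posterior list they were those of Hoxa10 (6.90 ± 0.39), Hoxc10, which shares its promoter region with a transcript of Hoxc5 (3.67 ± 0.98), Hoxd10 (3.22 ± 0.14) and Hoxa11 (2.28 ± 0.35). Of all 1231 protein-coding genes with at least 10 shared peaks, the 3 with most peaks per 100 kb were neighbours in the Hoxa cluster. Hoxa11 (chromosome 6, 52242106 to 52245810, mm10) had 97.0 per 100 kb, Hoxa10 had 91.0 and Hoxa9 had 85.7. The windows of these neighbours overlap, so that they share peaks.

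**Figure D3:**
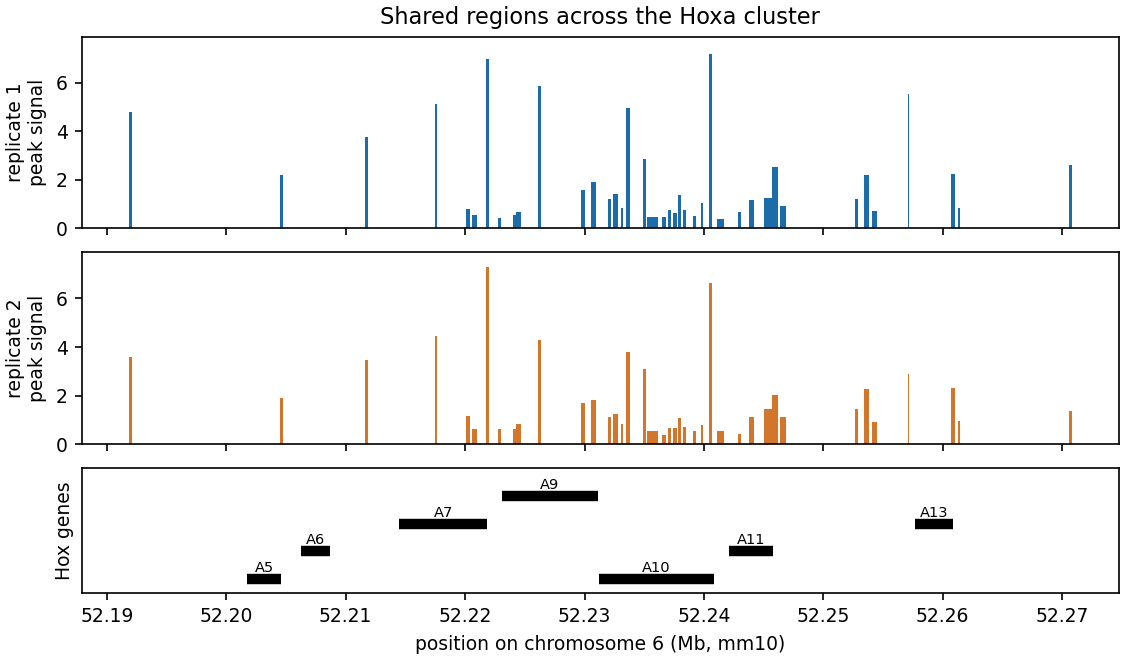
The upper panels give the peak signal of the shared regions (y axis) in replicate 1 (blue) and replicate 2 (orange) by position on chromosome 6 (x axis, Mb), and the lower panel gives the genes from Hoxa5 to Hoxa13, labelled A5 to A13. Regions lie most densely from Hoxa9 to Hoxa11, which have 85.7 to 97.0 shared peaks per 100 kb.

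Other genes among the 20 with the densest peaks included Kdm6b, a histone demethylase gene (59.7 per 100 kb), Tbx2, a T-box factor gene (57.8), Junb, an AP-1 subunit gene (57.8), Foxa1, a forkhead factor gene (57.1), Id2 (55.7), Id3 (49.4), Zfp503 (54.6) and Irf2bp2 (54.5). Zfp36 (59.7) and Zfp36l2 (54.1) encode proteins that bind AU-rich mRNA, and Gadd45b (54.2) is a stress response gene. Others were Midn (73.1), Gm37419 (64.6), Atp5d (55.2), 9130213A22Rik (48.8) and Prdx2 (47.5). Atp5d lies next to Midn and Prdx2 next to Junb, so that these pairs share peaks too. The densities of the 20 genes moved by more than the spread of the replicates in 82 of 140 alternatives, so their size depends on the processing. Density is per length of gene body and flanks, so that peaks near a short gene weigh more than as many near a long gene.

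The 10 strongest shared regions outside promoters were mostly exonic or intronic. The strongest lay in an exon of Cers5 on chromosome 15 (99735661 to 99736060, mm10), with a signal of 38.2 ± 0.89 (SD, n = 2), 10.2 kb from the TSS of Cox14. The next lay in exons of Lars2 on chromosome 9 (123461901 to 123462100; 34.4 ± 7.3) and Ubqln1 on chromosome 13 (58177621 to 58177820; 21.7 ± 2.6), and in intergenic sequence on chromosome 6 (49236421 to 49236620; 27.4 ± 5.6), 21.6 kb from the TSS of Igf2bp3. A pair of regions lay in an intron of Mid1 on the X chromosome (169997921 to 169998240 and 169998261 to 169998420), the first with a signal of 23.3 in replicate 1 and 16.7 in replicate 2, the second with 18.6 ± 3.7. Another lay in an intron of Il31ra on chromosome 13 (112578161 to 112578320; 22.3 ± 7.6). The last 3 lay 14.5 kb from the TSS of Zfp395 on chromosome 14 (65343681 to 65344020; 16.4 ± 2.9), in an exon of C87436 on chromosome 6 (86472201 to 86472520; 15.9 ± 0.47) and in an intron of Gm20388 on chromosome 8 (121585461 to 121585700; 15.6 ± 2.2). Of these 10 regions, 5 had at least 1 near-identical copy elsewhere in the genome.

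Motif content was used to ask which transcription factor families mark the regions outside promoters. Windows of 200 bp at 45542 shared regions were set against as many random windows of the same GC content outside peaks, by Fisher's exact test with adjustment over 32 motifs. The motif of the insulator protein CTCF showed the highest odds ratio: 8.96% of windows held it, against 0.0900% of random windows (odds ratio 109). With replicate 1 alone the odds ratio was 55.4, with replicate 2 alone 71.6, and with windows of 100 bp 196. The motif of REST, the repressor of neuronal genes, was set as a control and followed (odds ratio 68.7, adjusted p = 7.35e-38, Fisher's exact test). The full palindromic NFI motif came next (odds ratio 21.3, adjusted p = 1.82e-20, Fisher's exact test). Only 2 random windows held the REST motif, and its odds ratio was 43.1 with replicate 1 alone and 33.8 with replicate 2 alone. AP-1 lay in 12.4% of windows against 2.95% (odds ratio 4.63). The adjusted p for CTCF and AP-1 were too small for double precision. The motif of the epithelial GRHL factors was more frequent as well, in 3.72% against 1.79% (odds ratio 2.12, adjusted p = 1.19e-71, Fisher's exact test). TEAD, the DNA-binding partner of YAP, had an odds ratio of 2.18 (adjusted p = 2.20e-126), the steroid receptor palindrome 2.41 (adjusted p = 2.13e-21) and the single NFI site 2.06 (adjusted p = 6.71e-302, Fisher's exact test for each). Of the E-box motifs, CAGCTG had an odds ratio of 1.71 (adjusted p = 1.71e-202), while the ZEB and SNAI motif CAGGTG was less frequent than in random windows (odds ratio 0.770, adjusted p = 9.49e-53), both by Fisher's exact test.

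In all, 25 motifs were more frequent and 3 less frequent than in GC-matched windows at an adjusted p under 0.05. The 25 include motifs set as controls, among them that of HNF4, a hepatocyte factor (odds ratio 1.46, adjusted p = 0.00662, Fisher's exact test). The REST motif was set as a control too, but a repressor of neuronal genes can act outside neurons. Its frequency is therefore no measure of false calls. Since the HNF4 motif passed, passing alone does not show that a factor acts in the bladder. The HNF4 call was lost with the stricter lists (1.04), the stronger 50% of peaks (1.02), equal numbers of peaks (1.10) and windows 1 kb to either side (1.14). For AT-rich motifs the result depended on the background. The FOX motif had an odds ratio of 1.85 (adjusted p = 1.29e-74, Fisher's exact test) against GC-matched windows and 0.961 against windows 1 kb to either side of the same regions, which had 45.3% GC against 52.6% in the regions. The GATA motif went from 1.09 to 0.654, MEF2 from 1.77 to 0.812 and CArG, the site of serum response factor, from 1.19 to 0.983. Against the neighbouring windows FOX (adjusted p = 0.141), MEF2 (adjusted p = 0.0707) and CArG (adjusted p = 0.817) did not pass the exact test, so their calls were lost rather than turned. The GATA call was also lost with the stronger 50% of peaks. The CArG call was also lost with replicate 2 alone (odds ratio 1.09), the stronger 50%, equal numbers of peaks and windows of 100 bp. HOX-PBX, more frequent than in GC-matched windows, had an odds ratio of 0.732. ZEB and SNAI turned the other way, from 0.770 to 1.17.

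At promoters the same test was run in 14940 promoter windows that could be matched on GC content, of 27030. REST matches lay in 36 of them and in 0 random windows. CTCF had an odds ratio of 28.2 there, NRF1 18.4 (adjusted p = 2.41e-29), the full NFI motif 15.0 (adjusted p = 0.000871), ETS 14.4 (adjusted p = 8.52e-69), KLF and SP 1.70 (adjusted p = 3.93e-53) and NFY 1.64 (adjusted p = 6.10e-41, Fisher's exact test for each). NFY was less frequent than in random windows outside promoters (odds ratio 0.637, adjusted p = 1.71e-73), a call lost against windows 1 kb to either side (odds ratio 0.980, adjusted p = 0.419, Fisher's exact test for both).

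Footprints are short stretches inside an accessible region that are protected from cutting. Replicate 1 had 331596 and replicate 2 had 200630, each with a median width of 10 bp. Of the replicate 2 footprints 63.6% overlapped one of replicate 1, and of the replicate 1 footprints 35.9% overlapped one of replicate 2, against 0.325% and 0.194% by chance (one-sided permutation p = 0.001, the smallest that 1000 shifts can give). Within shared regions 65.5% of the replicate 2 footprints overlapped one of replicate 1, against 40.7% when they were placed at random in the same regions (permutation p = 0.001).

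Motif matches centred in 117771 shared footprints were set against windows of equal width in the same accessible regions. CTCF matches lay in 3.67% of footprints and 0.00764% of windows (odds ratio 498). The size of this ratio rested on 9 windows with a match, and it was 95.1 with replicate 1 alone and 74.1 with replicate 2 alone. NRF1 had an odds ratio of 133 (adjusted p = 1.20e-113, Fisher's exact test), ETS of 10.8 (adjusted p = 4.01e-75), single NFI sites of 2.82 (adjusted p = 3.84e-217) and NFY of 2.55 (adjusted p = 8.87e-109). The NRF1 ratio rested on 3 windows and was 46.7 with replicate 1 alone and 423 with replicate 2 alone. ETS had 6.13 and 5.36 with replicate 1 and replicate 2 alone, and 3.24 against windows beside the same footprints. Against those windows the NFY call was lost (odds ratio 1.07, adjusted p = 0.0703, Fisher's exact test). KLF and SP had an odds ratio of 7.51, with an adjusted p too small for double precision, as for CTCF. REST matches lay in 179 footprints and full NFI matches in 80, and in 0 of 117771 windows for both. AP-1 matches lay in 0.594% of footprints and 0.484% of windows (odds ratio 1.23), and its direction turned against windows beside the same footprints (odds ratio 0.753). GRHL did not pass the test (odds ratio 0.962, adjusted p = 0.854), but was less frequent than in windows beside the same footprints (odds ratio 0.719, adjusted p = 0.000116, Fisher's exact test for both). FOX (0.219), the steroid receptor palindrome (0.306), GATA (0.503), HOX-PBX (0.666) and TEAD (0.845) had odds ratios under 1, each at an adjusted p under 0.05 by Fisher's exact test. The TEAD call was lost with either replicate alone (0.910 with replicate 1 and 0.951 with replicate 2). The steroid receptor palindrome had 0.491 with replicate 2 alone and 0.159 against windows beside the footprints. In all, 13 of the 32 motifs were more frequent and 6 less frequent in footprints than in windows.

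**Figure D4:**
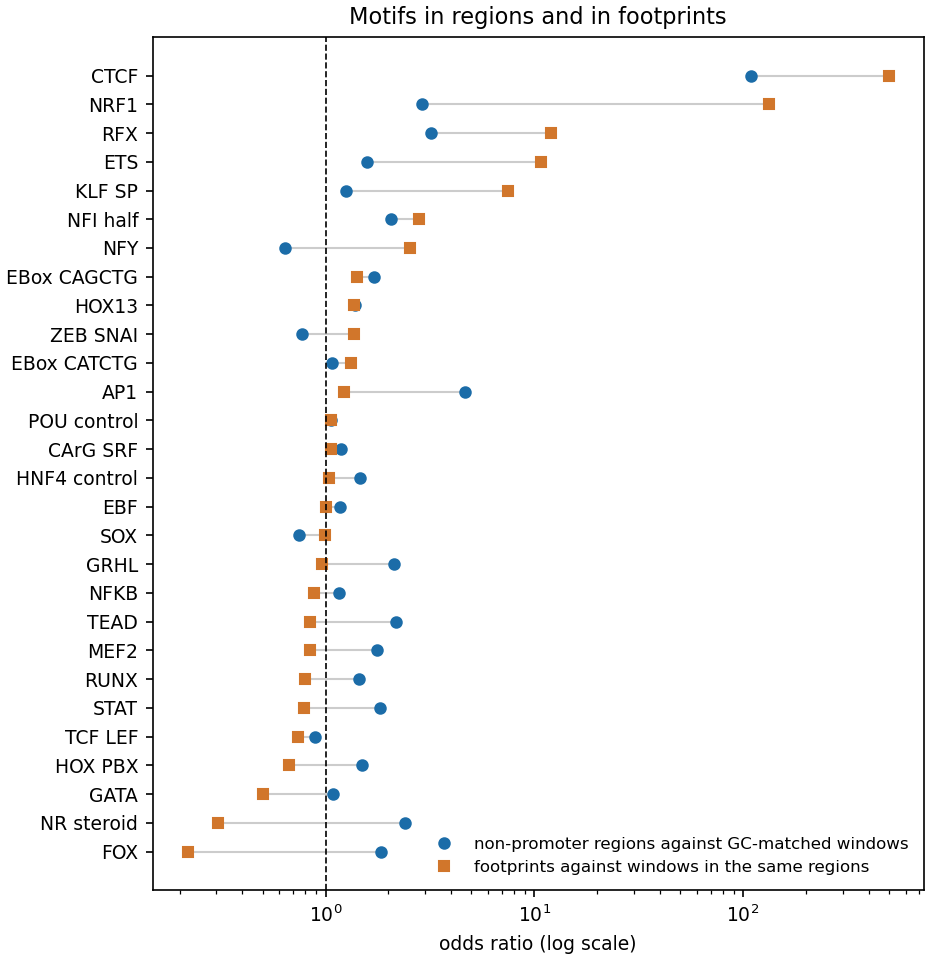
The points give odds ratios on a log axis (x axis) for 28 motifs (y axis), in shared regions outside promoters against GC-matched windows (blue circles) and in shared footprints against windows in the same accessible regions (orange squares), and the dashed line marks an odds ratio of 1. CTCF lies at 109 and 498, AP-1 at 4.63 and 1.23 and FOX at 1.85 and 0.219.

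The last comparison set replicate 1 against replicate 2 at open promoters, each scaled to its median over shared regions. With 1 library on each side it describes these libraries, and no test of conditions was made. The median log2 ratio of replicate 1 over replicate 2 was -0.14 over all open promoters. Urothelial promoters stood apart, with a median of 0.10 against -0.13 in random lists matched on signal, at the 99.93 percentile of 10000 such lists. They were above 0 at 14 of 26 genes, and at 19 of 26 when scaled to housekeeping promoters, with the same percentile. Smooth muscle promoters had a median of -0.07 (percentile 85.4), stromal promoters -0.24 (percentile 14.1), endothelial promoters -0.38 (percentile 6.30) and immune promoters -0.47 (percentile 3.74). Of the 18 lists with an estimate, urothelium alone lay outside the central 95% of random lists. No adjustment over the 18 lists was made, and chance alone can place 1 of so many outside that range. With the strongest peak within 2500 bp of the TSS its percentile was 89.7, inside that range.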

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

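Over 235 results and 1395 alternatives, 1193 counted as the same, 62 as weaker, 25 as stronger, 97 as moved and 18 as reversed. Called results were the same if direction and call held, and weaker if the call was lost. Uncalled results were the same if they stayed uncalled, whichever their direction, so the 18 leave out such changes of direction. Numbers of calls were the same within a set factor. Values without a test moved if they changed by more than the replicate spread. Of the 97 moved values, 82 were peak densities of the 20 named genes. For the signal correlation that bound was a 95% interval across regions, and for the FDR Jaccard index a small fixed value. All 10 alternatives for peak overlap and all 28 for the genomic distribution kept direction and call. The stricter peak list was chosen after seeing the data for 3 results, the genomic distribution, peak density and region motifs. The log2 signal correlation of 0.949 was 0.942 with the stronger 50% of peaks, 0.947 with equal numbers of peaks and 0.966 for the signal as deposited. Lists with more open promoters went from 7 to 4 with the stronger 50% of peaks, and lists with fewer went from 5 to 6 with the stronger 50% and to 2 with TSS windows of 2500 bp. Lists with a higher peak density went from 6 to 1 with the stricter list, 3 with the stronger 50% and 2 with equal numbers, and lists with a lower density from 0 to between 1 and 1 with a single replicate, which was the Y-linked list both times. The lists outside the central 95% in the replicate difference went from 1 to 0 with the strongest peak within 2500 bp. The X to autosome ratio was 0.370 and the Y ratio 0.0134 with the stricter list, and the FDR Jaccard index was 0.581 on autosomes only.

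Motifs less frequent in regions went from 3 to 6 against windows 1 kb to either side. Against those windows, odds ratios moved to the other side of 1 for CArG (0.983), GATA (0.654), FOX (0.961), MEF2 (0.812), HOX13 (0.603), HOX-PBX (0.732), POU (0.602) and ZEB and SNAI (1.17), but CArG, FOX and MEF2 did not pass the test there, and HOX13 and POU had not passed it before. In promoter regions they crossed 1 for GATA (0.981), NFY (1.64), EBF (0.920), CAGCTG (0.993) and CATCTG (0.741), where GATA, EBF and CAGCTG did not pass. Motifs less frequent in footprints went from 6 to 12 against flanking windows, where AP-1 (0.753) reversed and CArG (0.697), POU (0.417), GRHL (0.719), RUNX (0.716) and STAT (0.667), not called before, gained a call. EBF gained one in the other direction (1.62). POU also gained one with each replicate alone (0.612 to 0.704). The cause was not tested for these changes, nor for those with the stricter lists, which hold fewer peaks. The stronger 50% of footprints by score was not run, since the footprint value was constant. No paired analysis was possible because the design holds 1 group. Peaks of low signal limit the replicate overlap, and a promoter without a peak was not called at this depth, which does not show it closed.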

Other observations

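Gene families were defined by symbol prefix and chosen after the data were seen. They were set against all other protein-coding genes by Fisher's exact test, two-sided, adjusted over 18 families. Olfactory receptor promoters were open in 8 of 1135 genes and vomeronasal receptor promoters in 2 of 329 (adjusted p = 4.34e-151 for the latter, Fisher's exact test). These families, which encode chemosensory receptors, made up 1454 of the 7438 genes without an open promoter, and without them the open share of all genes was 70.8%. Of the open ones, Vmn1r4 had the highest signal (5.69 ± 0.39, SD, n = 2). Keratin-associated protein genes, which encode hair proteins, were open in 0 of 57 cases (adjusted p = 8.73e-27), beta-defensins in 3 of 42 (adjusted p = 6.98e-15) and cytochrome P450 family 2 genes in 10 of 49 (adjusted p = 2.45e-10), all by Fisher's exact test.

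Keratin genes were open less often than other genes, in 14 of 53 cases (adjusted p = 1.30e-08, Fisher's exact test) and so were claudin genes, which encode tight junction proteins, in 11 of 33 (adjusted p = 0.000257). Families of basic cell functions were open more often than other genes by the same exact test: NADH dehydrogenase subunits in 43 of 43 cases (adjusted p = 7.46e-08), ribosomal proteins in 87 of 98 (adjusted p = 6.78e-07) and proteasome subunits in 47 of 50 (adjusted p = 7.75e-06). Collagens (35 of 45), Wnt ligands (14 of 19), Fox factors (32 of 44), Sox factors (15 of 19), T-box factors (8 of 13), integrins (18 of 24), voltage-gated potassium channels (14 of 17) and Kruppel-like factors (15 of 17) did not pass the test.

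Of the tests of explanations below, 4 were chosen only after their results were seen: windows beside the same footprints, the position of footprints, the intervals of single motifs and copies on chromosomes alone. Urothelial promoters were relatively stronger in replicate 1, and a candidate explanation is GC content and signal strength. After a linear trend on both was removed over all open promoters, the list's median log2 ratio was 0.18, at the 99.31 percentile of random lists. It lay above 0.15, the upper end of their central 95%, which argues against that trend as the whole cause. GC content was taken in 1 kb around each gene's most upstream TSS, while the signal came from the strongest peak at any TSS. For genes with several TSSs an effect of GC content may thus be removed only in part. The list was picked because it alone lay outside the central 95% before the trend was removed. The percentile is not adjusted for that choice. A larger urothelial share of nuclei in replicate 1 was tested at regions away from urothelial genes: those with a GRHL match had a median log2 ratio 0.0717 above matched regions without one (95% interval 0.05 to 0.09, permutation p = 0.002, the smallest possible), which met the prediction. The condition that the shift be specific was added after this result was seen: CTCF regions shifted by 0.11 and REST regions by 0.25, and neither is urothelial, so a urothelial share cannot be told apart from a wider difference between the libraries. A difference between the animals, labelled as a male in replicate 1 and a pool of 3 in replicate 2, stays open and untested, and the pattern itself ended with the strongest peak within 2500 bp (percentile 89.7).

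The strongest shared regions outside promoters may draw reads from near-identical copies. Of the 10, 5 had another copy at 90% identity over 80% of their length, against 9 of 200 random shared regions (4.5%; Fisher's exact p = 0.000129, two-sided). For 6 of those 9 the copy lay on unplaced or alternative sequence alone, and with chromosomes alone the counts were 5 of 10 and 3 of 200 (1.5%; Fisher's exact p = 4.09e-06), which is consistent with this for those 5: the regions in Lars2, in the Il31ra intron, near Igf2bp3 and the pair in Mid1. The pair in Mid1 lies at a single locus and counts in full towards the 5, the lowest number set beforehand for this explanation. Its regions had 2 and 6 other copies, whose chromosomes were not recorded. A copy on Y in sequence that X and Y share would be an allele, and was not told apart from a duplicate. If the pair had such alleles alone, the number set beforehand would not be met. Some random regions with a copy are neighbours too, and the region near Zfp395 was also drawn among the 200. Both exact tests treat the regions as independent, so their p-values are only a rough guide. The other 5, the region in Cers5 among them, had no such copy, and none of the 10 had a copy in the mitochondrial genome. No biological explanation was tested, since the design holds no second group.

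A set of 6 motifs, those of GATA, FOX, TEAD, HOX-PBX and the steroid receptors among them, was more frequent in regions and less frequent in footprints than in their backgrounds. A concentration of footprints at promoters is argued against by their position: 52.3% of shared footprints lay within 1 kb of a TSS, against 60.8% of windows (SE of the difference 0.164 percentage points). Away from promoters 5 of the 6 still had odds ratios under 1 at an adjusted p under 0.05, all but TEAD (0.955). Surrounding GC content was 58.6% at footprints and 58.4% at windows. Against windows matched on it, 4 of the 6 still had odds ratios under 1 at an adjusted p under 0.05. For GATA, FOX and the steroid receptors the upper 95% bounds were 0.679 or lower. This argues against surrounding GC content as the whole cause for these 3. The base composition of the footprints themselves was not matched, so the test does not bear on it. TEAD had an odds ratio of 1.02 (95% interval 0.878 to 1.18) instead of 0.845. HOX-PBX had 0.750 (95% interval 0.545 to 1.03) instead of 0.666, so that its call was lost while its ratio moved little. Both intervals hold 1. That of TEAD lies above its first ratio, as the prediction for surrounding GC content asked, while that of HOX-PBX does not. The prediction was written for both together and so was not met. The lower frequency of TEAD also ended away from promoters, so the match on GC content is not the only one that removed it. For HOX-PBX surrounding GC content cannot be told apart from other causes. A concentration of footprints in strong regions is argued against by windows beside the same footprints, where 6 of 6 stayed under 1. Against windows 1 kb to either side of the regions, the higher frequency of GATA and HOX-PBX itself reversed (0.654 and 0.732), and that of FOX was lost (0.961, adjusted p = 0.141, Fisher's exact test). No biological explanation was tested, since the design holds no second group.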
